A study of Mus musculus with 36 samples.

How the data were processed

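Gene expression was measured by droplet sequencing of 3' transcript ends in single cells from mouse brain, in 36 libraries. Per the labels' protocols, a 3 mm piece of cortex and hippocampus around the contusion was taken, digested with collagenase and freed of dead cells before loading. The deposited files hold, per the file headers, counts of unique molecular identifiers (UMIs) per gene and cell barcode, written by Cell Ranger, with neither scaling nor log transformation. The submitters' processing notes name Cell Ranger 6.1.2, Seurat and the mouse build mm10, while the file headers name versions 3.0.2, 4.0.0 and 7.1.0. The version was 3.0.2 for the 6 mo libraries, 7.1.0 for replicate 4 at 7 d and 4.0.0 for all others. The lowest total of any barcode was 395 to 775 UMIs, so barcodes had been filtered before deposit. Most libraries carry 31053 genes and the 7 d libraries 32285, and the 30406 genes on every list were used. Gene positions are those of the GENCODE vM21 annotation of GRCm38, the same build, matched on gene identifiers.

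Groups and replicate numbers were taken from the sample titles. Designs, tests, gene lists, cell class markers, the rule for the genes named and the first set of alternatives were fixed before the data were examined. No pair of libraries of a group was a single library deposited again: the lowest chi-square per degree of freedom over 63 pairs was 12.07. Of all 630 pairs of libraries, 40 pairs among 11 libraries shared barcodes at over 5 times the median rate. The most was 2957 against 35.03 by chance, between female CCI replicate 3 and naive female replicate 2, so counts were also made without barcodes that were deeper in another library.

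Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were retained, 386173 in all. Doublets were scored per library with Scrublet as run by scanpy 1.11.5, and the highest-scoring 0.8% per 1000 retained barcodes were left out, which left 346833 cells, 3010 to 19928 per library. Up to 1500 cells per library, 54000 in all, were scaled to 10000 UMIs, log-transformed, reduced to 30 principal components of 2000 variable genes, and clustered with the Leiden algorithm (leidenalg 0.10.2, resolution 1, 15 neighbours, seed 11), without batch correction. Every other cell took the class most common among its 15 nearest clustered cells. The 29 clusters were called X-like from the fixed markers. Cluster 7 stayed unnamed with 3 of 12 microglial markers raised, against 1 in clusters 6 and 9. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.

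The replicate was the library. Counts were summed per library and class, leaving out sums over fewer than 20 cells, and tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment over all genes tested, false discovery rate 0.05). Each of the 10 comparisons was fitted on its own groups, in microglia-like and endothelial-like cells, and for male CCI at 24 h also in astrocyte-like and oligodendrocyte-like cells, giving 22 counts of genes. The fit of ipsilateral against contralateral libraries had the mouse as a block, since the titles give each contralateral library the mouse of an ipsilateral one. The sex comparison was the interaction of sex label and injury. CPM values are scaled by TMM library sizes in the fits and are plain CPM in the figures. The ± after a CPM is the SD over libraries, and the ± after a log2 change its SE. A gene without UMIs in a group was set against 3 counts over that group, which covers counting error only.

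Named were the 6 largest rises and the 4 largest falls past the threshold with an average log2 CPM of at least 5 and no overlap between the libraries of both groups. For same-mouse pairs the rule asked for the same sign in every pair, and for the interaction it had no overlap rule. Predicted genes, Rik, mitochondrial, ribosomal and hemoglobin genes and markers of other classes were left out. Up to 4 members of each list with the smallest p past the threshold, and Xist and Ddx3y, were added, and not every gene that the rule names is printed. The 22 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 measured members, and again with an estimated correlation. Calls adjusted over the list alone are given beside those over all genes.

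Shares of classes were compared with exact permutation tests of the difference of means, two-sided, adjusted over all classes and comparisons together, with signs flipped within mice for both sides of the same mice.

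The alternatives fixed beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, stricter cells (at least 500 genes, at most 10% mitochondrial UMIs), doublets kept, at least 50 cells, all groups in one fit, a replicate block, each library left out in turn, a term for library series (16 and under against 17 and over), and another denominator of the share. Chosen after seeing the data were fits without the 2 libraries whose sex transcripts went against their labels, without barcodes deeper in another library, without endothelial cluster 23, without clusters 11, 14 and 28 of the microglia-like class, and with cluster 7 counted in that class. Also chosen then were fits without genes under 0.1 of their level in another class, without genes moved alike in 3 classes, and without endothelial-like cells holding over 10 UMIs of homeostatic microglia genes. For each count, up to 40 splits of the same libraries into groups of the same sizes were refitted. Results for 1 gene are not reported here.

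Whether equal replicate numbers pair libraries was checked by correlating their deviations from the group means, which had to exceed 0.1 in every pair. This held for CCI against naive in microglia-like cells (0.103 to 0.422 over 6 pairs, of which 5 correlated best with their own number) and for CCI+HS against CCI in endothelial-like cells (0.343 to 0.484 over 3 pairs, 2 of them best with their own). The pairing there comes from the data, since the labels tie a number to no litter, batch or day.

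The gene test was tested on simulated data, with 200 genes changed 1.5-, 2- or 4-fold among counts drawn from each comparison's means and library sizes. Simulated male CCI against naive recovered 83.6% of 2-fold and 98.5% of 4-fold changes in microglia-like cells (11960 genes, 10 false calls), and 62.7% and 97.0% in endothelial-like cells (10055 genes, 4 false calls). For rCHI against naive these were 47.8% and 93.9% in microglia-like cells (12346 genes) and 25.4% and 93.9% in endothelial-like cells (10049 genes), with 3 false calls in each. For CCI+HS against CCI they were 47.8% and 90.9% (11989 genes, 2 false calls) and 13.4% and 78.8% (10646 genes, 1 false call). For the interaction they were 31.3% and 74.2% (12602 genes, 6 false calls) and 4.5% and 80.3% (11228 genes, 5 false calls). Changes of 1.5-fold were recovered in 38.8% of cases in microglia-like cells for male CCI and in 4.5%, 3.0% and 0.0% for rCHI, CCI+HS against CCI and the interaction.

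For male CCI against naive, microglia-like sums came from 1418 to 6677 cells and endothelial-like sums from 142 to 869. Astrocyte-like sums came from 28 to 248 and oligodendrocyte-like sums from 22 to 88, which limits what these classes can show. Antibody tags in replicate 4 of the 7 d group were not used to divide its cells.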

Results

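Gene expression was measured in single cells from the brains of adult mice, in 36 droplet libraries that fall into 9 groups. Controlled cortical impact (CCI), in which a piston strikes the exposed cortex and leaves a contusion, was sampled in males at 24 h in 6 libraries from the injured side and in 3 libraries from the mirror-image side of 3 of the same mice. The other injured groups were females 24 h after CCI (3 libraries), males 24 h after CCI with hemorrhagic shock (CCI+HS, 3 libraries), males 24 h after repetitive closed head injury (rCHI, 3 libraries), and males 7 d and 6 mo after CCI (4 libraries each). Uninjured tissue came from 7 libraries labelled naive male and 3 labelled naive female. The libraries held 18187843 to 132069996 UMIs and 3209 to 26713 barcodes, with a median of 906 to 6931 UMIs per retained cell. Apart from tying each contralateral library to the mouse of an ipsilateral one, the labels do not say whether replicates are separate animals, so the p-values measure only the spread between these libraries, which may be technical.

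After filtering, 346833 cells were assigned to cell classes through 29 clusters. Microglia-like cells made up 45.2% of them, choroid plexus-like cells 17.5% and endothelial-like cells 7.72%, followed by 26115 monocyte/macrophage-like, 25510 neutrophil-like, 10094 dendritic-like, 8721 astrocyte-like, 7132 pericyte-like, 5554 T or NK-like and 4539 oligodendrocyte-like cells. The submitters state 10 broad cell types and 23 populations; the classes here were rebuilt from marker genes, so a difference from that count may come from the names. Unnamed cluster 7, 2.10% of cells, held a median of 0.347 of the library median UMIs per cell. No microglial marker was among its 10 leading genes, as in clusters 4, 6, 9, 11, 24 and 28 of the microglia-like class. Clusters 11 and 14 of that class were led by more markers of another class than of microglia, 1 of oligodendrocytes against 0 and 2 of neurons against 1. They hold most of the 7 d and 6 mo cells of the class, so values of the class at these times are those of the numbered clusters given beside them. Xist, transcribed from the inactive X chromosome of females, and Ddx3y, on the Y chromosome, went against 2 labels. The library labelled naive male 7 held 41471 Xist and 148 Ddx3y UMIs, and the library labelled naive female 1 held 4 Xist and 5465 Ddx3y UMIs. Both were kept under their labels, and values without them are given where they moved a count by over 1.5 times.

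How far blood leukocytes entered the injured tissue was asked with the share of infiltrating myeloid cells, the monocyte/macrophage-like and neutrophil-like cells together. In males 24 h after CCI these cells made up 42.8% ± 8.47 (SD, n = 6) of retained cells, against 0.232% ± 0.123 (SD, n = 7) in naive tissue. The difference was 42.5 percentage points (exact permutation test, two-sided, p = 0.000583, the smallest these 13 libraries can give, adjusted p = 0.0157). The 2 lineages contributed alike, with monocyte/macrophage-like cells at 22.8% ± 7.07 and neutrophil-like cells at 20.0% ± 11.5 of the cells. Dendritic-like cells rose from 0.308% to 7.39% and T or NK-like cells from 0.705% to 1.73% (adjusted p = 0.0256 or lower), while the microglia-like share fell from 61.3% ± 10.4 to 25.1% ± 4.86 (adjusted p = 0.0256). The dendritic-like class was named from cluster 2, with 2 dendritic markers and 1 monocyte/macrophage marker among its 10 leading genes. No dendritic marker but 5 of 12 monocyte/macrophage markers were raised there over other clusters, so its name is uncertain. It was not counted as infiltrating. After CCI+HS infiltrating cells made up 33.5% ± 7.01 (n = 3, adjusted p = 0.0388 against naive), and after rCHI 0.171% ± 0.0814 (n = 3), with an exact permutation p of 0.45 against naive. On the contralateral side they made up 4.43% ± 2.80 (n = 3, 1.43% to 6.97%, adjusted p = 0.0388). Without any 1 of their 10 libraries CCI+HS and the contralateral side differed from naive by 29.38 to 36.25 and 2.93 to 5.70 points, at the smallest p that 9 libraries can give (adjusted p = 0.0536 to 0.1103). In females the share was 41.2% ± 4.80 after CCI and 0.0688% ± 0.0196 in naive libraries, without overlap, but 3 libraries against 3 cannot reach an exact permutation p below 0.1. It stood at 0.804% ± 0.733 at 7 d (adjusted p = 0.0639) and 0.530% ± 0.363 at 6 mo (adjusted p = 0.153). The difference was 0.572 points at 7 d (0.216 without replicate 4) and 0.298 points at 6 mo (0.135 without replicate 1). It passed at 7 d without replicate 2 (adjusted p = 0.0363) and at 6 mo without replicate 4 (0.0352). At 7 d the monocyte/macrophage-like part stood at 0.605% ± 0.425 against 0.1305% ± 0.0826 in naive males (adjusted p = 0.0388) and the neutrophil-like part at 0.199% (adjusted p = 0.75). Microglia-like clusters 11 and 28 are not counted in the 7 d share and may hold infiltrating cells. Ms4a7 was in 33% and 22.1% of their cells, 58.7% of monocyte/macrophage-like cluster 10 and at most 11.2% of other microglia-like clusters. Shares are of all cells with at least 500 UMIs, so added infiltrating cells lower every other share. Median UMIs per microglia-like cell were 2233 in naive males and 4320 after CCI.

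**Figure D1:**
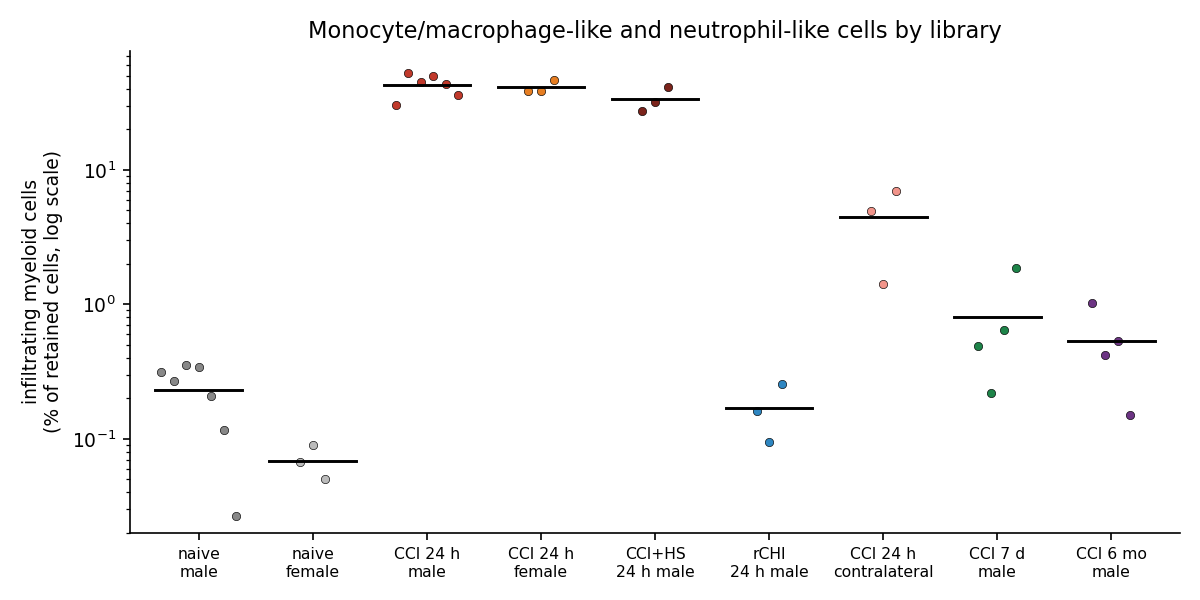
Share of retained cells in the monocyte/macrophage-like and neutrophil-like classes together (percent, y axis, logarithmic scale) by group (x axis), with 1 point per library and a bar at each group's mean. All CCI and CCI+HS libraries taken at 24 h from the injured side lie above every contralateral library, and the rCHI libraries lie within the naive male range.

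Microglia of the injured tissue were compared with those of naive tissue 24 h after CCI in males. Inflammatory and lipid droplet genes rose as lists in microglia-like cells. Homeostatic genes fell and disease-associated and proliferation genes rose, but these lists did not pass with an estimated correlation. P2ry12 (chromosome 3, 59216272 to 59262871, minus strand, mm10), the purinergic receptor of surveying microglia, fell from 1853 ± 286 CPM (SD, n = 7) to 304 ± 114 CPM (n = 6), a 6.097-fold fall (log2 change -2.61 ± 0.22 SE, adjusted p = 3.11e-08). Spp1 (chromosome 5, 104435118 to 104441050, plus strand), which encodes osteopontin, rose 242-fold from 5.37 to 1227 ± 300.2 CPM (log2 7.92 ± 0.42, adjusted p = 3.21e-10), and stayed at 0.107 of its level in monocyte/macrophage-like cells. In all, 7642 of 11907 tested genes passed an edgeR quasi-likelihood test at a false discovery rate of 0.05, 3751 higher and 3891 lower, and 1353 rose and 1344 fell at least 2-fold. The largest other rises were in Ch25h (186-fold), Adam8 (141-fold), Lilr4b (125-fold), Mmp12 (115-fold) and Msr1 (101-fold). The largest other falls were in Crebrf (6.33-fold), Thrsp (5.85-fold) and Lst1 (5.79-fold), and these 8 genes each had an adjusted p of 1.29e-07 or lower. Adam8 rose 243-fold without naive replicate 2. Naive cells of this class fell mostly in clusters 5, 8 and 19 and injured ones in clusters 4 and 6.

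Of the 12 measured homeostatic microglia genes 10 fell, 10 adjusted over the list alone (camera adjusted p = 4.28e-05; adjusted p = 0.162 with an estimated correlation). Siglech fell 4.39-fold, P2ry13 2.95-fold and the transcription factor Sall1 2.68-fold. Of 17 disease-associated microglia genes 11 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 7.10e-05; adjusted p = 0.162 with an estimated correlation). Lpl rose 50.7-fold to 1030 ± 164 CPM and Lgals3 rose 42.1-fold. Inflammatory genes rose in 12 of 16 and fell in 2, 12 and 2 adjusted over the list alone (camera adjusted p = 2.30e-13; adjusted p = 0.0276 with an estimated correlation). Tnf rose 9.68-fold to 1967 ± 168 CPM, Il1rn 59.6-fold and Ptgs2 21.3-fold. All but 1 of the 16 proliferation genes rose, and all 16 adjusted over the list alone (camera adjusted p = 1.67e-05; adjusted p = 0.419 with an estimated correlation), led by the replicative helicase subunits Mcm2 (23.9-fold), Mcm5 (21.5-fold) and Mcm6 (16.4-fold). Hypoxia and glycolysis genes rose in 9 of 14 and fell in 1, 9 and 1 adjusted over the list alone (camera adjusted p = 0.000353; adjusted p = 0.162 with an estimated correlation), among them Pgk1 (4.65-fold). Interferon genes rose in 11 of 18 with 1 lower, 11 and 1 adjusted over the list alone (camera adjusted p = 0.00609; adjusted p = 0.462 with an estimated correlation), among them Cxcl10 (10.4-fold). Lipid droplet and cholesterol genes rose in 6 of 12, 6 adjusted over the list alone, with none lower (camera adjusted p = 6.84e-05; adjusted p = 0.0276 with an estimated correlation), among them Plin2, a lipid droplet coat protein (11.8-fold). The lists for complement (adjusted p = 0.133), heme and iron (0.256), immediate early genes (0.256), MHC class I (0.403), MHC class II (0.578), edema channels and transporters (0.408) and phagocytosis (0.947) did not pass. Hmox1 rose 2.85-fold and Slc40a1 fell 3.97-fold.

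**Figure D2:**
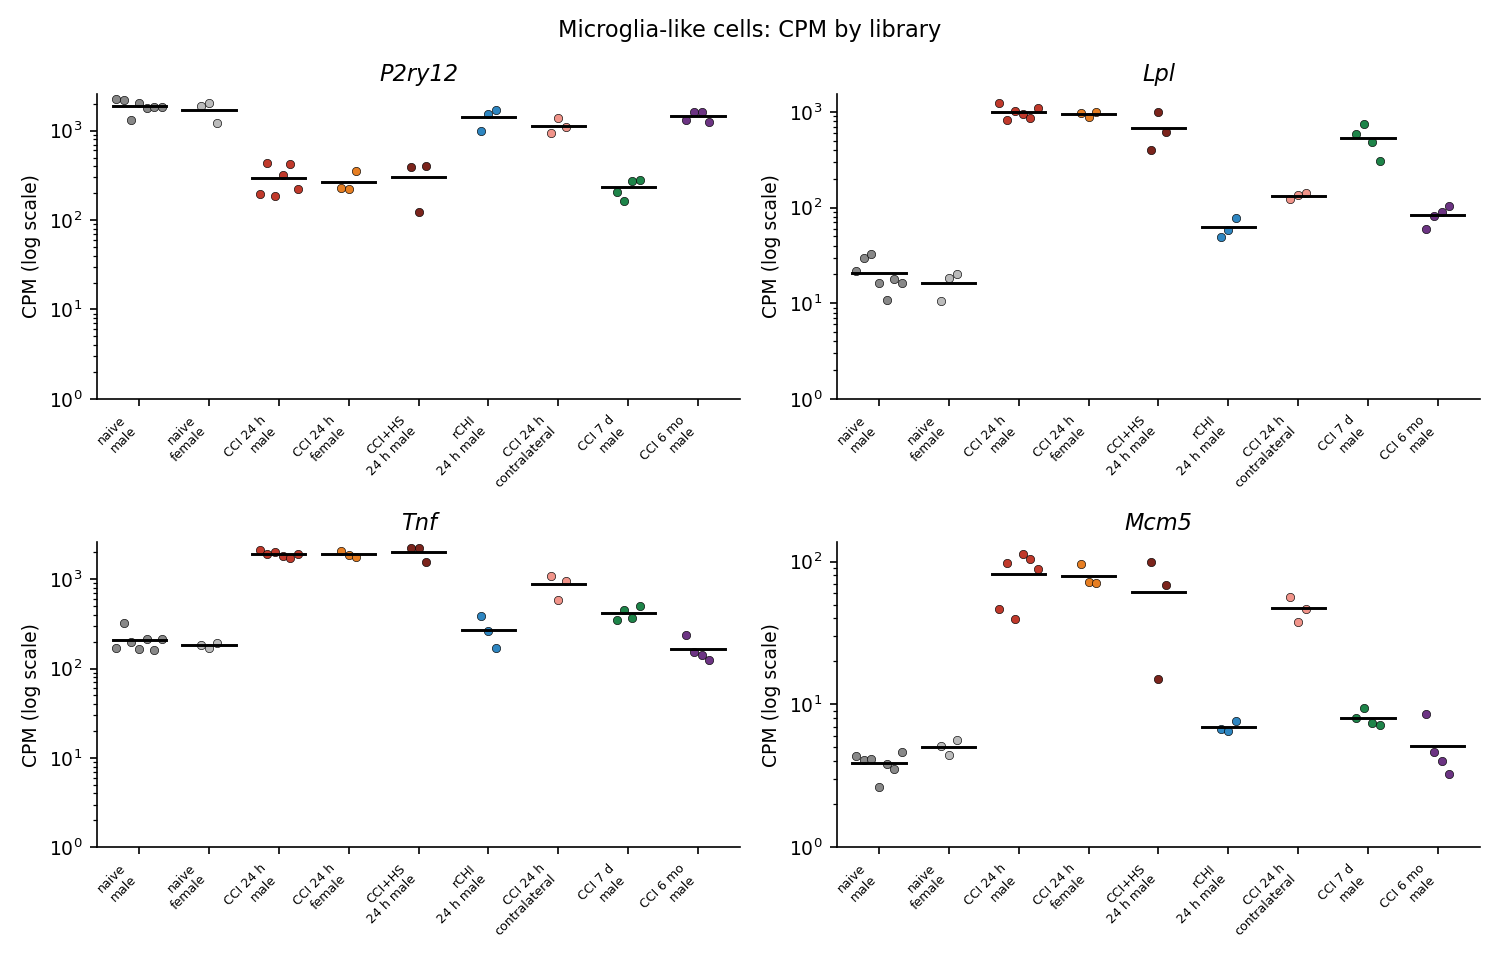
CPM of P2ry12, Lpl, Tnf and Mcm5 in microglia-like cells (y axes, logarithmic scale) in each library by group (x axis), with a bar at each group's mean. P2ry12 is lower and Lpl, Tnf and Mcm5 are higher in each library from the injured side 24 h after CCI, in both sexes, than in any naive library, and the contralateral libraries lie between them in Lpl.

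In endothelial-like cells the same injury raised genes of endothelial activation and of vessel sprouting. Ackr1, an atypical chemokine receptor of venules (chromosome 1, 173331886 to 173333750, minus strand), rose 58.7-fold, from 5.83 ± 3.90 CPM (SD, n = 7) to 314 ± 211 CPM (n = 6; log2 5.88 ± 0.48, adjusted p = 3.98e-07). Lcn2, the iron-siderophore carrier lipocalin (chromosome 2, 32384633 to 32388252, minus strand), rose 55.2-fold to 440 ± 221 CPM (log2 5.79 ± 0.41, adjusted p = 7.57e-08), and Selp, P-selectin, which captures rolling leukocytes, rose 54.2-fold to 58.7 ± 39.7 CPM (adjusted p = 3.19e-06). Activation and adhesion genes rose in 8 of 12, and 9 rose and 1 fell adjusted over the list alone (median log2 change 3.15, camera adjusted p = 1.51e-18; adjusted p = 0.00246 with an estimated correlation). The other largest rises were in Spp1 (76.2-fold, at 0.0195 of its level in monocyte/macrophage-like cells), Timp1 (63.4-fold), Scgb3a1 (26.1-fold) and Lrg1 (21.2-fold), each with an adjusted p of 9.01e-06 or lower. Without naive replicate 2 Spp1 rose 119-fold, and without the library labelled naive male 7 Selp rose 163-fold. Of 12 angiogenesis genes 5 rose and none fell, 5 adjusted over the list alone (camera adjusted p = 8.76e-08; adjusted p = 0.0406 with an estimated correlation), including placental growth factor Pgf (20.9-fold), apelin Apln (19.02-fold to 129 ± 49.6 CPM) and adrenomedullin Adm (7.92-fold). The blood-brain barrier list did not move together: the tight junction gene Cldn5 was at 2181 CPM after CCI and 2474 CPM in naive cells, and the transferrin receptor Tfrc fell 1.66-fold (adjusted p = 0.00311). Of 9 Wnt pathway genes 1 fell, Axin2 (1.85-fold, adjusted p = 0.00342; camera adjusted p = 0.0388 for the list; adjusted p = 0.436 with an estimated correlation).

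In total 1573 of 10073 tested genes passed in endothelial-like cells, 744 of them higher. Among the lower ones were microglial transcripts: 11 of 12 homeostatic microglia genes fell, and 12 adjusted over the list alone (median log2 change -2.52, camera adjusted p = 5.61e-19; adjusted p = 0.0571 with an estimated correlation), with Crybb1 9.42-fold, Slc2a5 8.20-fold, P2ry13 8.10-fold and Selplg 7.02-fold lower. Endothelial-like cells with over 10 UMIs of that list made up 27.6% of the class in naive males and 8.18% after CCI. Without them 722 genes passed, 467 higher and 255 lower, and Selplg had a log2 change of 0.008 (adjusted p = 0.995). Without cluster 23, whose leading genes are those of fenestrated vessels, 2459 genes passed.

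**Figure D3:**
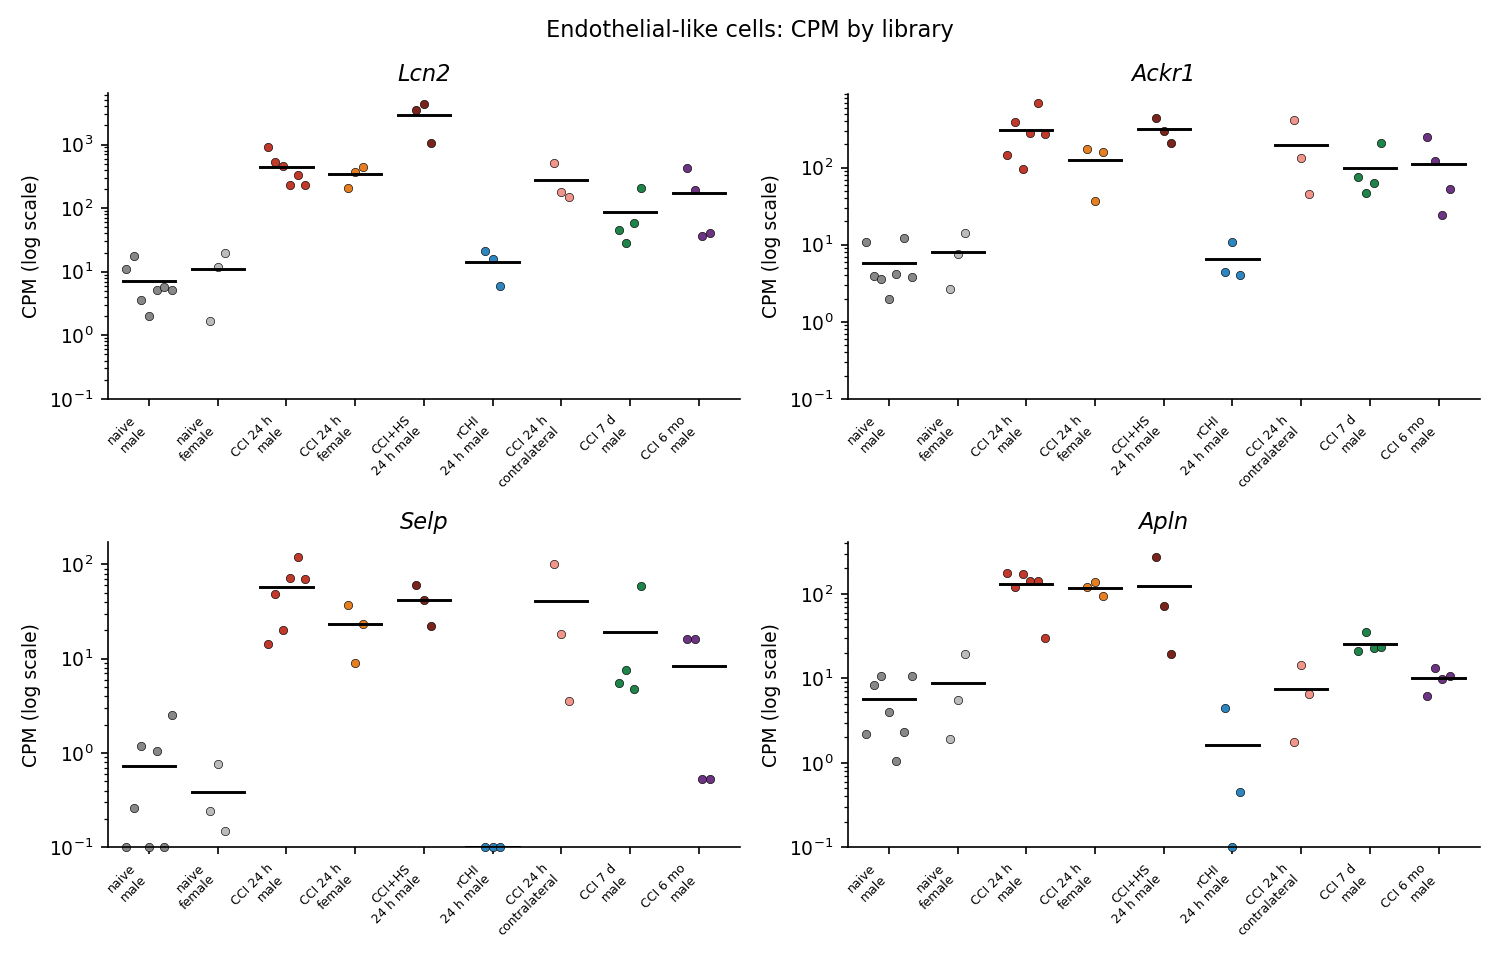
CPM of Lcn2, Ackr1, Selp and Apln in endothelial-like cells (y axes, logarithmic scale with 0 drawn at the lower edge) in each library by group (x axis), with a bar at each group's mean. Lcn2 and Ackr1 are higher in every library from the injured side 24 h after CCI or CCI+HS than in any naive library, and so they are in the contralateral libraries.

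Astrocyte-like and oligodendrocyte-like cells were tested for the same comparison, with 28 to 248 and 22 to 88 cells per library. In astrocyte-like cells all 11 measured reactive astrocyte genes rose, 11 adjusted over the list alone (median log2 change 5.88, camera adjusted p = 8.89e-72; adjusted p = 3.40e-05 with an estimated correlation). Serpina3n, a serine protease inhibitor (chromosome 12, 104406729 to 104414329, plus strand), rose 58.9-fold to 535 ± 321 CPM (n = 6, against 7.58 ± 8.65 in 7 naive libraries), Timp1 115-fold, the hyaluronan receptor Cd44 63.8-fold and Tm4sf1 60.9-fold (adjusted p of 1.31e-07 or lower). S1pr3 stood at 159 ± 66.9 CPM and Osmr at 130.0 ± 41.4 CPM. All naive libraries held 0.309 and 0.829 CPM from 1 and 2 UMIs, too few for a fold change. Hmox1 rose 23.0-fold and C4b 13.7-fold. Of 12 astrocyte homeostasis genes 1 fell, Glul, encoding glutamine synthetase (2.28-fold, from 2368 ± 353 to 1040 ± 121 CPM, adjusted p = 0.000606), and 4 adjusted over the list alone (camera adjusted p = 0.117). The largest falls were in Unc13c (8.38-fold), Ephx2 (3.72-fold), Rmst (3.38-fold) and Id4 (3.37-fold). In all 225 of 3254 genes passed, 154 higher and 71 lower, and Serpina3n rose 112-fold without naive replicate 2. The count was 130 without CCI replicate 1, 142 without naive replicate 1 and 363 without the library labelled naive male 7.

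In oligodendrocyte-like cells 45 of 2540 genes passed (4 libraries against 5), 34 higher and 11 lower. Serpina3n rose 16.3-fold to 740.1 ± 338 CPM (log2 4.03 ± 0.50, adjusted p = 0.000261), C4b 12.7-fold and Cebpd 11.9-fold. Gpd1 (9.58-fold), Cela1 (9.52-fold) and Gadd45b (7.83-fold) followed. Of 9 disease-associated oligodendrocyte genes 3 rose, Serpina3n, C4b and Cdkn1a, and 6 adjusted over the list alone (camera adjusted p = 1.49e-09; adjusted p = 0.0184 with an estimated correlation). None of the 10 myelin genes passed, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0694), with Mbp at 3755 CPM after CCI and 5318 CPM in naive cells. Of 5 measured homeostatic microglia genes 1 fell, P2ry12 (9.54-fold, adjusted p = 0.0454, at 0.0708 of its level in microglia-like cells), and 4 adjusted over the list alone (median log2 change -1.79, camera adjusted p = 6.69e-06; adjusted p = 0.1103 with an estimated correlation). Ptn fell 2.46-fold, from 1761 ± 131 to 713 ± 87.6 CPM (adjusted p = 0.000693), and Jph4, Omg and Smco3 fell 2.24- to 3.07-fold. The calls for Smco3, Omg and Cdkn1a were lost without single libraries (adjusted p of 0.0742, 0.0631 and up to 0.102), and that for P2ry12 without CCI replicate 1 or 3 (0.0777 and 0.153). Without CCI replicate 2 P2ry12 fell 31.2-fold, and without naive replicate 2 Serpina3n rose 52.7-fold and Cela1 14.3-fold.

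CCI with hemorrhagic shock models polytrauma, and was compared first with naive tissue. In microglia-like cells Spp1 rose 198-fold to 1011 ± 546 CPM (n = 3, against 5.35 ± 4.19 in 7 naive libraries, log2 7.63 ± 0.51, adjusted p = 3.08e-07), Msr1 187-fold, Adam8 161-fold, Lilr4b 102-fold and the monocyte chemoattractant Ccl7 73.1-fold. P2ry12 fell 6.00-fold, Upk1b 12.2-fold, the interleukin-7 receptor Il7r 8.28-fold, Thrsp 7.84-fold and Lst1 7.23-fold, each with an adjusted p of 6.18e-05 or lower. Without CCI+HS replicate 2 Ccl7 rose 15.3-fold, Adam8 54.5-fold, Lilr4b 60.5-fold and Msr1 80.7-fold, and without naive replicate 2 Adam8 rose 276-fold and Ccl7 118-fold. In all 5860 of 12389 genes passed, 3194 higher and 2666 lower. Clusters 4 and 6 held 15.1% and 11.6% of all CCI+HS cells, and clusters 5 and 8, where naive cells of the class mostly fell, 3.84% and 1.25%. Inflammatory genes rose in 12 of 16 with 1 lower, 12 and 1 adjusted over the list alone (camera adjusted p = 3.37e-11; adjusted p = 0.311 with an estimated correlation). Homeostatic genes fell in 10 of 12, 10 adjusted over the list alone (camera adjusted p = 1.46e-05; adjusted p = 0.311 with an estimated correlation). In endothelial-like cells Lcn2 rose 401-fold to 3078 ± 1940 CPM (log2 8.65 ± 0.55, adjusted p = 8.82e-07), Ackr1 58.8-fold, Scgb3a1 37.3-fold and Selp 34.9-fold. The granulocyte growth factor Csf3, with no UMI in the naive libraries, was at least 944-fold higher against 3 counts over that group (165 ± 193 CPM, adjusted p = 0.00402), and its fitted log2 change of 11.50 was 9.65 without CCI+HS replicate 2 and 12.11 without replicate 3. Scgb3a1 rose 18.1-fold without CCI+HS replicate 1 and Selp 104-fold without the library labelled naive male 7. Activation and adhesion genes rose in 8 of 12, and 10 adjusted over the list alone (median log2 change 3.92, camera adjusted p = 3.36e-28; adjusted p = 0.00456 with an estimated correlation). The alkaline phosphatase Alpl fell 3.97-fold, Car5a 4.43-fold and Gkn3, an arterial gene, 8.66-fold, calls lost without CCI+HS replicate 2 (adjusted p = 0.0589, 0.0748 and 0.1003, with Gkn3 4.75-fold lower). Without replicate 3 they fell 6.73-, 11.1- and 16.01-fold. The endothelial count of 383 of 10653 genes, 282 higher and 101 lower, was 229, 223 and 644 without CCI+HS replicates 1, 2 and 3, 226 without the library labelled naive male 7, and 220 without the cells that hold over 10 microglial UMIs.

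What shock adds to the contusion was tested directly, CCI+HS against CCI. In microglia-like cells 2 of 11984 genes passed: Cd72, an inhibitory receptor, fell 2.75-fold, from 349.8 ± 52.6 CPM (n = 6) to 127 ± 12.3 CPM (n = 3; log2 -1.46 ± 0.15, adjusted p = 0.00621). The sulfotransferase Sult1a1, which lies outside the rule for named genes and was chosen after its values were seen, rose 3.51-fold (adjusted p = 0.00621). Both calls were lost without CCI+HS replicate 1 (adjusted p = 0.107 and 0.0673) and that of Cd72 also without replicate 3 (0.116), with totals of 0, 6 and 1 genes without replicates 1, 2 and 3. DESeq2 called 53. No interferon gene passed over all genes, 4 of 18 were lower adjusted over the list alone, and the list as a whole was lower (median log2 change -0.75, camera adjusted p = 3.93e-12; adjusted p = 0.488 with an estimated correlation). Ifit3 was at 5.27 ± 2.98 CPM after CCI+HS and 17.9 ± 10.1 CPM after CCI (adjusted p = 0.593). MHC class II genes gave the same picture, with none past the test over all genes, 2 lower adjusted over the list alone and H2-Aa at 3.63 and 16.6 CPM (camera adjusted p = 0.000483; adjusted p = 0.488 with an estimated correlation). In endothelial-like cells edgeR called 0 of 10643 genes, with 288 at an unadjusted p under 0.05. Lcn2 stood at 3112 ± 1953 CPM after CCI+HS and 439 ± 220 CPM after CCI (log2 2.84 ± 0.46, adjusted p = 0.315), and it was the 1 gene that DESeq2 called (adjusted p = 8.03e-05). Without CCI+HS replicate 3 edgeR called 2 genes, Lcn2 and Csf3 (adjusted p = 0.0264). The infiltrating share was 9.31 points lower after CCI+HS (exact permutation p = 0.155, adjusted p = 0.312). Its monocyte/macrophage-like part stood at 10.4% ± 3.54 against 22.8% ± 7.07, without overlap (exact permutation p = 0.0357, adjusted p = 0.126), and its neutrophil-like part at 23.1% ± 8.43 against 20.0% ± 11.5 (adjusted p = 0.818). No overlap was seen for dendritic-like cells either, at 3.05% against 7.39% (exact permutation p = 0.0119, adjusted p = 0.0536).

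Repetitive closed head injury, a model of sports concussion without a contusion, was compared with naive tissue at 24 h. Proliferation genes were higher in microglia-like cells as a group: 14 of 16 were higher adjusted over the list alone and none past the test over all genes (median log2 change 1.03, camera adjusted p = 1.68e-22; adjusted p = 0.0196 with an estimated correlation). The topoisomerase Top2a stood at 26.5 ± 1.66 CPM (SD, n = 3) against 8.36 ± 4.75 CPM (n = 7; log2 1.70 ± 0.36, adjusted p = 0.355), the mitotic cyclin Ccnb1 at 3.05 against 0.943 CPM (adjusted p = 0.355) and survivin Birc5 at 6.74 against 2.14 CPM (adjusted p = 0.462). Lpl stood at 61.3 ± 15.5 against 20.9 ± 7.97 CPM (log2 1.55 ± 0.27, adjusted p = 0.295), and of 17 disease-associated genes 2 were higher adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.366 with an estimated correlation). Immediate early and homeostatic genes were lower as lists, with none past the test over all genes or adjusted over the list alone (median log2 change -0.44 and -0.12, camera adjusted p = 0.000475 and 0.0110; adjusted p = 0.366 for each with an estimated correlation). By edgeR 0 of 12295 genes passed, 841 had an unadjusted p under 0.05, and DESeq2 called 14, all higher, among them Lpl (adjusted p = 0.00260), Top2a (0.0390) and Ccnb1 (0.0445). Without rCHI replicate 1 edgeR called 1 gene, Nes, and without naive replicate 5 it called S100a8 and S100a9, which were named after their values were seen. In endothelial-like cells edgeR called 0 of 10046 genes, 480 had an unadjusted p under 0.05, DESeq2 called 0, and without the library labelled naive male 7 edgeR called 1, Zbtb16 (adjusted p = 0.00389), named after its values were seen.

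The uninjured hemisphere was sampled to see how far from the contusion cells respond. Contralateral microglia-like cells carried the replication genes: Mcm5 (chromosome 8, 75109569 to 75128439, plus strand) rose 11.8-fold, from 3.91 ± 0.613 CPM (n = 7 naive libraries) to 46.7 ± 10.8 CPM (n = 3; log2 3.55 ± 0.15, adjusted p = 7.76e-09), Mcm2 12.4-fold and Mcm6 8.42-fold. Of 16 proliferation genes 15 rose, and 16 adjusted over the list alone (median log2 change 2.34, camera adjusted p = 6.92e-38; adjusted p = 0.0552 with an estimated correlation). Inflammatory genes rose in 11 of 16, and 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.91e-09; adjusted p = 0.137 with an estimated correlation), with Tnf up 4.17-fold to 869 ± 278 CPM and the chemokine Ccl12 3.96-fold. Spp1 rose 25.2-fold to 129 ± 90.3 CPM, 0.0117 of its level in monocyte/macrophage-like cells (15.2-fold without contralateral replicate 1), Lpl 6.35-fold to 132 ± 9.01 CPM, and Cxcl10 3.83-fold, each with an adjusted p of 2.08e-05 or lower or, for Cxcl10 and Ccl12, 0.0001 or lower. P2ry12 fell 1.70-fold, from 1899 ± 294 to 1119 ± 173 CPM (adjusted p = 0.00757, and 0.0718 without contralateral replicate 1). Among the largest falls were Lars2 (2.82-fold) and Tnfrsf17 (2.50-fold). In all 2287 of 12427 genes passed, 1305 higher and 982 lower, and the count was 758 without contralateral replicate 1 and 1080 without replicate 3.

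Contralateral endothelial-like cells changed in few genes. Ackr1 rose 35.9-fold to 192 ± 192 CPM (adjusted p = 0.000637), Lcn2 34.4-fold to 271 ± 202 CPM (adjusted p = 0.000158) and Scgb3a1 4.39-fold (adjusted p = 0.000637). Without contralateral replicate 1 Ackr1 rose 15.7-fold and Lcn2 19.3-fold. By edgeR 17 of 11321 genes passed, 16 higher and 1 lower, and 507 had an unadjusted p under 0.05. Without naive replicates 2, 5 and 6 and the library labelled naive male 7 the count was 9, 11, 11 and 4, and without contralateral replicate 2 it was 8. Of 9 measured activation and adhesion genes 3 rose, Lcn2, Ackr1 and the secreted glycoprotein Lrg1, none of them an adhesion molecule, and 8 adjusted over the list alone (median log2 change 0.96, camera adjusted p = 5.39e-25; adjusted p = 0.0140 with an estimated correlation). The call for Lrg1 (13.8-fold, adjusted p = 0.0173) was lost without any of 5 libraries, contralateral replicate 1, naive replicates 2, 5 and 6, or the library labelled naive male 7 (adjusted p up to 0.114). Proliferation genes rose in 1 of 7, Mcm5, and 5 were higher adjusted over the list alone (camera adjusted p = 4.33e-10; adjusted p = 0.0140 with an estimated correlation).

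Both sides of the same 3 mice were then compared with the mouse as a block. Ipsilateral microglia-like cells stood above contralateral ones in Mmp12 (14.6-fold), Adam8 (14.3-fold), Lilr4b (12.8-fold), Spp1 (12.4-fold, 1355 ± 313 against 127 ± 89.3 CPM, n = 3 each, log2 3.63 ± 0.36, adjusted p = 0.000166), Ccl7 (12.3-fold) and Lgals3 (9.96-fold). They stood below contralateral ones in Ifitm10 (3.81-fold), P2ry12 (3.41-fold), Matk (3.22-fold) and Siglech (3.11-fold). In all 6270 of 12826 genes passed, 3278 higher and 2992 lower. Homeostatic genes were lower in 11 of 12, 11 adjusted over the list alone (camera adjusted p = 5.54e-10; adjusted p = 0.388 with an estimated correlation). Proliferation genes, which had risen on the far side too, were higher still in 15 of 16, and 16 adjusted over the list alone (camera adjusted p = 5.03e-08; adjusted p = 0.509 with an estimated correlation), with Mcm2 up 2.39-fold. In endothelial-like cells some sprouting genes differed between the sides, with Pgf 17.2-fold and Apln 14.1-fold higher on the injured side. Of 13 angiogenesis genes 5 were higher, 6 adjusted over the list alone (camera adjusted p = 7.07e-07, and 0.378 with an estimated correlation). Spp1 was 16.8-fold, Timp1 8.31-fold, Emp1 7.32-fold and the neutrophil chemokine Cxcl2 7.05-fold higher, and the lactate transporter Slc16a1 2.11-fold lower (adjusted p = 0.00553). There 772 of 11845 genes passed, 318 higher and 454 lower, and the count was 2081 without the mouse of ipsilateral replicate 4 and 132 without that of replicate 5. Without the mouse of replicate 4 microglial Spp1 was 18.9-fold and endothelial Spp1 31.4-fold, Timp1 12.6-fold and Apln 8.93-fold higher. Without that of replicate 5 microglial Mmp12 was 26.8-fold and endothelial Spp1 10.3-fold and Timp1 4.50-fold higher. The infiltrating share differed by 38.6 points, with an exact sign-flip p of 0.25, the smallest that 3 mice allow.

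Females were studied in a separate experiment with their own naive libraries. In microglia-like cells Spp1 rose 471-fold to 1688 ± 1381 CPM (n = 3, against 4.53 ± 4.01 in 3 naive libraries, adjusted p = 3.58e-05), Ch25h 336-fold, Mmp12 277-fold, Lpl 58.7-fold to 944 ± 34.0 CPM and Tnf 10.4-fold. P2ry12 fell 6.42-fold, Crybb1 6.93-fold, Thrsp 6.53-fold and Selplg 4.39-fold, all of these genes with an adjusted p of 3.58e-05 or lower. Spp1 rose 256-fold without CCI replicate 2 and 744-fold without naive replicate 3, and Ch25h 528-fold without the library labelled naive female 1. In all 5829 of 11727 genes passed, 2912 higher and 2917 lower. Naive female cells of the class lay mostly in clusters 5 and 8 (7705 and 3120 cells) and injured ones in clusters 4 and 6 (2098 and 2076 cells, with 682 and 453 in clusters 5 and 8). All 16 proliferation genes rose, 16 adjusted over the list alone (median log2 change 3.33, camera adjusted p = 6.80e-22; adjusted p = 0.187 with an estimated correlation). MHC class I presentation genes fell in 8 of 11, 8 adjusted over the list alone (median log2 change -0.85, camera adjusted p = 0.000100; adjusted p = 0.161 with an estimated correlation). H2-T23 was 3.77-fold lower, from 203 ± 0.241 to 53.9 ± 1.12 CPM, and the immunoproteasome subunit Psmb9 2.35-fold lower. In endothelial-like cells Selp rose 58.5-fold, Lcn2 27.2-fold to 332 ± 121 CPM, Adamts9 17.5-fold, Scgb3a1 16.98-fold, Ackr1 13.6-fold and Lrg1 11.8-fold. Without naive replicate 3 Lcn2 rose 50.6-fold and Ackr1 24.4-fold, and without naive replicate 2 Selp rose 95.5-fold. Activation and adhesion genes rose in 6 of 11 with 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 4.71e-11; adjusted p = 0.0977 with an estimated correlation). All 12 homeostatic microglia genes fell there, 12 adjusted over the list alone (median log2 change -2.82, camera adjusted p = 6.53e-16; adjusted p = 0.212 with an estimated correlation). Hk2, Lst1 and Rhoh fell 8.39- to 11.5-fold (13.03- to 31.7-fold without CCI replicate 3), and cells holding over 10 microglial UMIs made up 32.2% of naive and 9.87% of injured female endothelial-like cells. The endothelial count of 861 of 11364 genes was 219 and 535 without CCI replicates 1 and 2, 364 without the library labelled naive female 1, and 89 without the cells holding over 10 microglial UMIs.

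Whether the response to CCI differs between the sexes was tested as the interaction of sex and injury. By edgeR 0 of 12742 genes passed in microglia-like cells, with 1168 at an unadjusted p under 0.05 and 11 by DESeq2, and 0 of 11339 in endothelial-like cells, with 1104 and 47. MHC class I genes in microglia-like cells were lower after injury in females relative to males as a list (median log2 change -0.42, none past the test over all genes, 2 adjusted over the list alone, camera adjusted p = 0.000154; adjusted p = 0.504 with an estimated correlation). Log2 interactions were -0.77 ± 0.26 for H2-D1 and -0.60 ± 0.19 for Tap1 (adjusted p = 0.496 for both). In endothelial-like cells inflammatory genes were lower in the same sense, 5 adjusted over the list alone and none over all genes (median log2 change -1.38, camera adjusted p = 5.47e-09; adjusted p = 0.356 with an estimated correlation). The infiltrating share rose by 41.1 points in females and 42.5 in males, a difference of -1.40 points (exact permutation p = 0.784). Each naive group has 1 library whose sex transcripts went against its label, so these differences rest on labels in doubt.

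At 7 d after CCI the cells counted as microglia-like lay mostly in clusters 11 (30427 cells) and 28 (7354, from replicate 4 alone). Only replicate 4 used Cell Ranger 7.1.0, an effect not tested. There 7 and 11 of 12 microglial markers were each in over 50% of cells. The set most raised over other clusters was oligodendrocyte in cluster 11 (3 of 10) and erythrocyte in 28 (1 of 5). Of the 7 d cells of cluster 11, 92.9% held the oligodendrocyte transcript Mbp. Against naive microglia-like cells the 7 d cells stood higher in lipid-handling and interferon genes. Gpnmb, a lysosomal glycoprotein (chromosome 6, 49036546 to 49070929, plus strand), stood at 2047 ± 681 CPM (SD, n = 4) against 0.242 ± 0.363 CPM (n = 7; log2 12.94 ± 0.62, adjusted p = 1.14e-08; log2 14.30 without naive replicate 2). Spp1 stood at 13400 ± 2958 against 5.11 CPM. The apolipoprotein Apoc2, with no UMI in naive libraries, stood at 368 ± 91.1 CPM, at least 11070-fold higher against 3 counts over that group. Igf1 rose 271-fold to 409 ± 109.8 CPM and Axl 26.9-fold. Of 17 disease-associated genes 16 rose, 16 adjusted over the list alone (median log2 change 4.75, camera adjusted p = 2.23e-25; adjusted p = 0.0132 with an estimated correlation). All 18 interferon genes rose, 18 adjusted over the list alone (median log2 change 3.00, camera adjusted p = 2.23e-25; adjusted p = 0.0136 with an estimated correlation), including the antiviral Rsad2 (36.8-fold) and Oasl2 (28.1-fold). All 12 homeostatic genes fell, 12 adjusted over the list alone (camera adjusted p = 5.86e-12; adjusted p = 0.0163 with an estimated correlation), with P2ry12 6.89-fold lower. Lipid droplet genes rose in 9 of 12 with 1 lower, 9 and 1 adjusted over the list alone (camera adjusted p = 5.86e-12; adjusted p = 0.0228 with an estimated correlation). Phagocytosis genes rose in 8 of 13 with 1 lower, 8 and 1 adjusted over the list alone (camera adjusted p = 0.00172; adjusted p = 0.116 with an estimated correlation). In all 7740 of 13002 genes passed, 4152 higher and 3588 lower.

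Endothelial-like cells at 7 d stood higher in interferon genes. Free RNA as their source was not tested, but 46.8% of these cells in cluster 15 held the monocyte/macrophage transcript Lyz2, against 6.6% at 6 mo. All 18 interferon genes rose, 18 adjusted over the list alone (median log2 change 1.44, camera adjusted p = 2.81e-20; adjusted p = 0.0127 with an estimated correlation). The largest rise was in Ifi27l2a (14.2-fold, from 20.3 ± 6.37 to 298 ± 133 CPM, adjusted p = 2.27e-06), and Irf7 rose 3.13-fold and Oasl2 2.96-fold. The transcription factor Lef1 of the Wnt pathway rose 2.06-fold, from 163 ± 28.4 to 336 ± 80.2 CPM (adjusted p = 0.00192). Of 10 Wnt genes 5 rose, 5 adjusted over the list alone (camera adjusted p = 0.000394; adjusted p = 0.102 with an estimated correlation). The largest Wnt change, in Apcdd1 (25.5-fold, from 11.1 ± 5.07 to 288 ± 46.0 CPM), was 1 of those shared by unrelated cell classes. Barrier and transport genes rose in 5 of 13, and 7 adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.299 with an estimated correlation), among them Slc16a1 (2.83-fold) and the junction scaffold Tjp1 (1.88-fold). Ackr1 was 19.2-fold higher than in naive cells, and 12.55-fold without 7 d replicate 4. In all 1959 of 10759 genes passed, 1154 higher and 805 lower, and 1133 without replicate 3.

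The 7 d comparison also carries differences between libraries. Its gene models came from a longer list of 32285 genes. By over 2 on the log2 scale 200 genes moved the same way in microglia-like, endothelial-like and choroid plexus-like cells, 193 of them up. At 6 mo 53 did so, all up, and at 24 h after male CCI 50, of them 48 up. Those at 7 d include Apcdd1, the microglial Gpnmb, Apoc2 and Igf1, Rnasek (867-fold in microglia-like and 437-fold in endothelial-like cells), Mrpl53 and Atp6v0c (312- and 90.3-fold in endothelial-like cells) and, among falls, Ptp4a1 (77.7- and 54.6-fold) and Coro1b (18.1- and 11.03-fold). Rnasek rose 1442-fold in microglia-like cells without naive replicate 1 and 779-fold in endothelial-like cells without replicate 2, and Coro1b fell 16.55-fold in the latter without 7 d replicate 4. Without the 200 genes 7536 and 1790 genes passed. No naive library of the 7 d or 6 mo series was given, so time after injury cannot be told apart from library batch, and at 6 mo not from age either.

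At 6 mo 6549 of the 10303 cells counted as microglia-like lay in cluster 14, where 12 of 12 microglial markers were each found in over 50% of cells and 2 neuronal markers were among the leading genes. The cells of the class stood above naive ones in lipid-handling and interferon genes. Gpnmb stood at 205 ± 82.2 CPM (SD, n = 4) against 0.269 ± 0.407 CPM (n = 7; log2 9.46 ± 0.45, adjusted p = 1.06e-08; log2 10.82 without naive replicate 2), Spp1 rose 29.2-fold to 155 ± 77.8 CPM, Fabp5 24.2-fold, Lgals3 22.5-fold, Igf1 16.7-fold and the integrin Itgax 5.02-fold. Of 17 disease-associated genes 11 rose and 2 fell, 11 and 2 adjusted over the list alone (median log2 change 2.33, camera adjusted p = 3.07e-15; adjusted p = 0.0339 with an estimated correlation). Interferon genes rose in 12 of 18, 12 adjusted over the list alone, with none lower (camera adjusted p = 2.37e-06; adjusted p = 0.157 with an estimated correlation), among them Rsad2 (6.73-fold). Lipid droplet genes rose in 10 of 12 with 1 lower, 10 and 1 adjusted over the list alone (camera adjusted p = 7.52e-07; adjusted p = 0.0339 with an estimated correlation). Homeostatic genes fell in 9 of 12, 9 adjusted over the list alone (median log2 change -0.57, camera adjusted p = 0.000168; adjusted p = 0.156 with an estimated correlation), with Fcrls 2.08-fold and the growth factor receptor Csf1r 1.51-fold lower. The largest falls were in Fam71a (6.27-fold), Gadd45g (3.92-fold), Klhdc8b (3.23-fold) and Cirbp (3.04-fold). In all 5053 of 12644 genes passed, 2648 higher and 2405 lower. Neuronal transcripts rose too, Bc1 42.7-fold and Map2 39.0-fold (18.95- and 24.4-fold without 6 mo replicate 4), and 2268 genes passed without clusters 11, 14 and 28.

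Endothelial-like cells at 6 mo stood above naive ones in genes of activation and adhesion, with Lcn2 up 21.7-fold to 171 ± 182 CPM (adjusted p = 0.000102), Ackr1 21.03-fold, C4b 17.4-fold, Vcam1 2.80-fold and the interleukin-1 receptor Il1r1 3.40-fold. Without 6 mo replicate 1 Lcn2 rose 11.04-fold and Ackr1 12.2-fold. Of 9 activation and adhesion genes 7 rose and 1 fell, 7 and 1 adjusted over the list alone (camera adjusted p = 5.05e-05; adjusted p = 0.263 with an estimated correlation). Lef1 rose 2.13-fold and the efflux pump Abcb1a 1.69-fold to 748 ± 25.1 CPM, while Mfsd2a, a lipid transporter of the barrier, fell 2.00-fold, from 120 ± 21.3 to 60.1 ± 14.5 CPM (adjusted p = 0.000641). Inflammatory genes fell in 9 of 14 and rose in 2, 9 and 2 adjusted over the list alone (camera adjusted p = 0.00203; adjusted p = 0.424 with an estimated correlation), with Ccl2 9.99-fold lower. In all 3307 of 10945 genes passed, 1574 higher and 1733 lower, with Bc1 (14.1-fold, and 7.04-fold without 6 mo replicate 4) and Map2 (11.9-fold) among the higher and the microglial Gpr183, Hk2, Crybb1 and P2ry13 (14.6- to 19.1-fold) among the lower. Cells with over 10 microglial UMIs made up 2.11% of the class at 6 mo and 27.6% in naive males, and without them Crybb1 had a log2 change of -0.88 (adjusted p = 0.0617).

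At 6 mo shares of retained cells (56.4% to 86.7% of barcodes) differed from naive males (74.7% to 97.9%). Astrocyte-like cells made up 13.4% ± 4.52 (n = 4) against 1.88% ± 1.18 (n = 7), oligodendrocyte-like cells 4.60% against 0.498%, fibroblast-like cells 3.62% against 0.290%, pericyte-like cells 6.54% against 1.93% and T or NK-like cells 3.91% against 0.705%. Microglia-like cells, cluster 14 among them, made up 28.1% ± 0.918 against 61.3% (exact permutation p = 0.00303 for each of these 6 classes, the smallest these 11 libraries allow, adjusted p = 0.0256). At 7 d oligodendrocyte-like cells made up 3.12%, dendritic-like cells 2.30% and T or NK-like cells 2.32% (adjusted p = 0.0388 or lower). Of 135 share tests 29 passed at an adjusted p of 0.05 and 41 unadjusted.

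**Figure D4:**
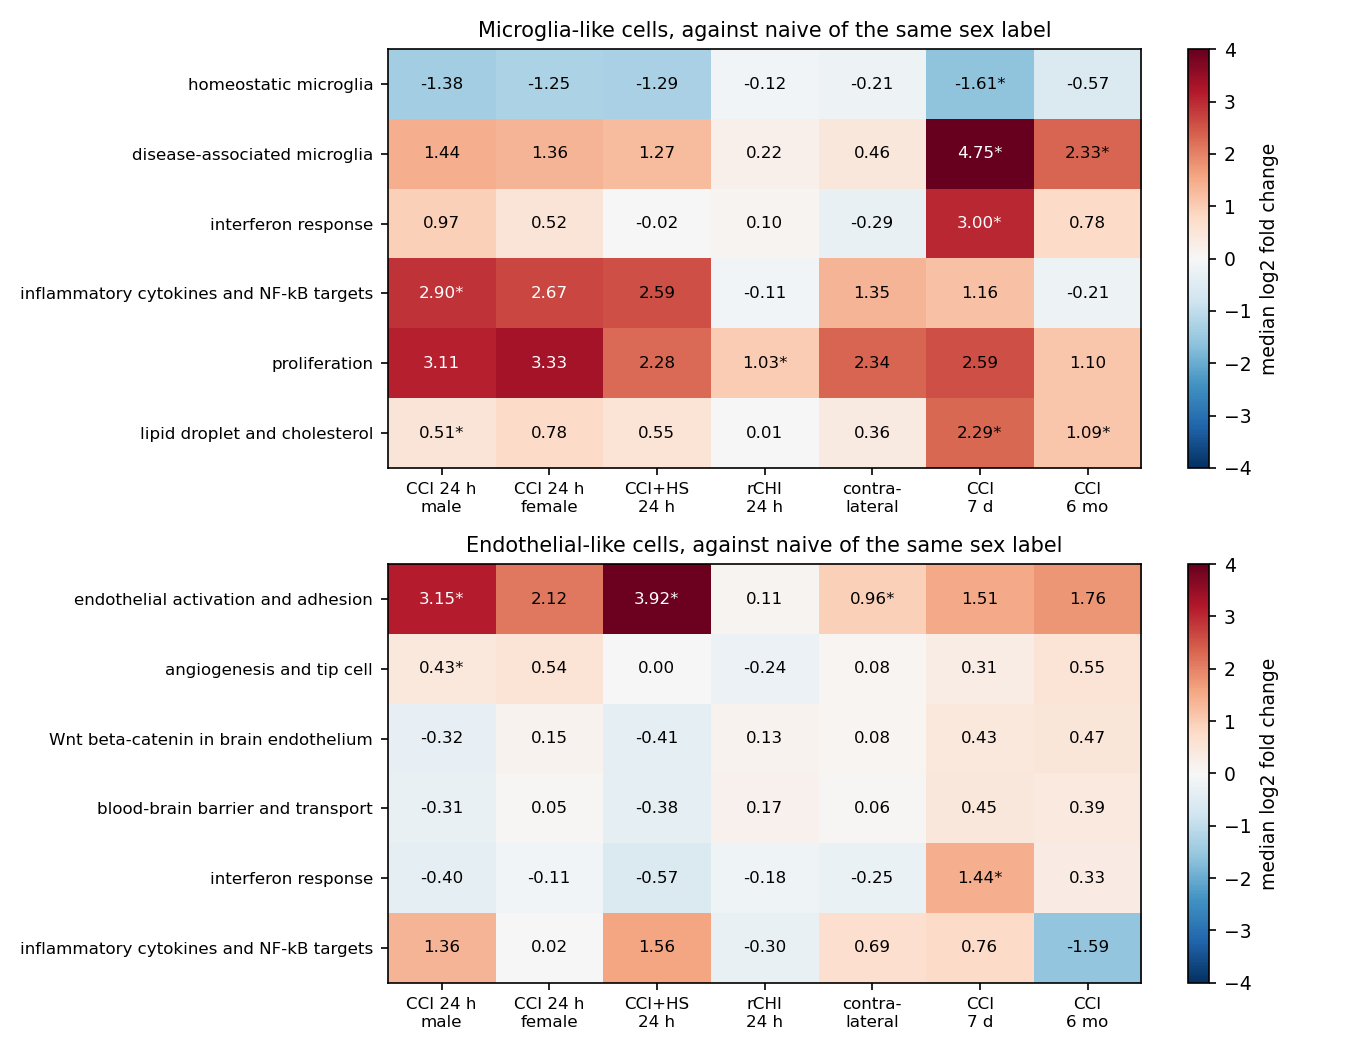
Median log2 fold change of 6 gene lists per panel (rows, not the same lists in both) in microglia-like and endothelial-like cells (panels). Columns are the comparisons against naive libraries. Values are printed in each cell and coloured from blue (lower) to red (higher), with an asterisk where camera's adjusted p with an estimated correlation is under 0.05. The interferon median is highest at 7 d in both classes, at 3.00 and 1.44. The homeostatic microglia median, drawn for microglia-like cells only, is below 0 in every column, from -1.61 to -0.12.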

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

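None of the tests in this part was chosen after its result was seen. Of 321 groups of 4 to 7 libraries tested, 35 held a library far from the others, where chance gives about 1 in 20. Each value below is the gap to the nearest other library divided by the range of the group. Naive male replicate 2 accounts for 9 of the 35 and naive male replicate 4 for 5, and no explanation of this was tested.

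Among shares of cells, male CCI replicate 1 stood apart in astrocyte-like cells (0.802; 1.82% against 0.389% to 0.673%) and naive male replicate 2 in oligodendrocyte-like cells (0.568; 1.25% against at most 0.669%). So did 6 mo replicate 1 in endothelial-like cells (0.869; 16.6% against 11.3% to 12.0%), 7 d replicate 2 in microglia-like cells (0.907; 75.7% against 58.9% to 60.5%) and 7 d replicate 4 in neutrophil-like cells (0.888; 0.666% against at most 0.0748%).

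In microglia-like cells naive male replicate 2 was the highest of its group for Adam8 (0.799), Lilr4b (0.801), Tnf (0.622), Ccl7 (0.571) and Gpnmb (0.815), replicate 4 the highest for Spp1 (0.621) and the lowest for Klhdc8b (0.684), replicate 1 the highest for Rnasek (0.660) and replicate 3 for Csf1r (0.639). Male CCI replicate 3 was the highest for Ifit3 (0.658), 6 mo replicate 4 the highest for Map2 (0.835) and 6 mo replicate 2 the lowest for Rsad2 (0.869). In endothelial-like cells male CCI replicate 6 was the lowest for Apln (0.684), naive male replicate 2 the highest for Rnasek (0.636), replicate 4 the highest for Gpr183 (0.680) and replicate 5 the lowest for Mfsd2a (0.575). At 7 d replicate 2 was the lowest for Mrpl53 (0.958), and replicate 4 was the lowest for Ifi27l2a (0.905; 100.1 against 354 to 381 CPM) and the highest for Coro1b (0.880). At 6 mo replicate 2 was the highest for Hk2 (0.865) and replicate 1 the lowest for Gpr183 (0.893).

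In astrocyte-like cells male CCI replicate 2 was the highest for Timp1 (0.629; 1176 against 183 to 552 CPM) and replicate 1 for S1pr3 (0.645). Among naive males replicate 3 was the highest for Timp1 (0.711), replicate 6 for Tm4sf1 (0.722) and Hmox1 (0.647), and replicate 2 for S1pr3 (1.000, where the other 6 libraries held no UMI). In oligodendrocyte-like cells naive male replicate 4 was the highest for Jph4 (0.728) and the lowest for Omg (0.860), and replicate 2 the highest for Serpina3n (0.718).

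Replicate 4 of the 7 d group also carries antibody tags that no comparison used. In 35.53% of its 12605 cells 1 tag gave at least 80% of at least 10 tag UMIs.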

How the results depend on the processing

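The fits without mismatched libraries, shared barcodes, single clusters, genes of other classes and mixed cells were chosen only after the results were seen. With at least 50 cells oligodendrocyte-like sums gave no value. Of 208 genes named, 180 kept their direction and their side of the threshold under every alternative that gave them a value, which most did not for all genes, and of 4699 values over genes and alternatives 4630 did, 60 passed no longer, 8 passed newly and 1 changed direction. That was Selplg in endothelial-like cells after male CCI, with a log2 change of 0.008 (adjusted p = 0.9954) without cells holding over 10 UMIs of the homeostatic microglia list, to which Selplg itself belongs. For the changes below the cause was not tested. Where an alternative was fitted and its count is not given, the count lay within 1.5 times of that in the report. Counts under DESeq2 size factors did so throughout. The term for library series was fitted for male CCI against naive only. All groups in one fit was not run for the contralateral side or between the sides.

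With the DESeq2 Wald test the counts in microglia-like cells were 14 for rCHI against naive, 53 for CCI+HS against CCI and 11 for the interaction of sex and injury. In endothelial-like cells they were 620 for CCI+HS, 1 for CCI+HS against CCI (Lcn2), 31 for the contralateral side, 496 between the sides and 47 for the interaction. In astrocyte-like and oligodendrocyte-like cells they were 471 and 122. With all groups in one fit the counts were 2 for rCHI (Nes and Lpl) and 10 for CCI+HS against CCI in microglia-like cells, and 708 for CCI+HS and 2982 at 7 d in endothelial-like cells. Without a filter on low counts they were 4 for CCI+HS against CCI (Lcn2, Hbb-bt, Hbb-bs and Fkbp5), 46 contralaterally, 1399 in females and 1594 between the sides in endothelial-like cells, and 567 and 237 in astrocyte-like and oligodendrocyte-like cells. With doublets kept they were 786 for CCI+HS, 97 contralaterally and 1996 between the sides in endothelial-like cells, 781 in astrocyte-like and 482 in oligodendrocyte-like cells. Stricter cells gave 93 in astrocyte-like cells, and the term for library series gave 77 in oligodendrocyte-like cells. Of 451 list tests, 192 passed at the preset correlation and 29 with an estimated one.

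With the replicate number as a block the counts in microglia-like cells were 2 for rCHI (S100a8 and Camp), 0 by edgeR for CCI+HS against CCI (248 at an unadjusted p under 0.05), 721 contralaterally and 5 for the interaction (1810022K09Rik, Kdm5d, Eif2s3y, Uty and Ddx3y). Endothelial counts were 961 for male CCI, 52 for CCI+HS, 40 contralaterally, 462 in females, 446 at 7 d and 1 for the interaction (Ddx3y). Ddx3y went against 2 labels, so interaction calls rest on labels in doubt. Astrocyte and oligodendrocyte counts were 629 and 10. Without the mouse block 231 endothelial genes passed between sides. Under the block the differences in infiltrating share were 42.5 points after male CCI, 33.14 after CCI+HS and 4.119 contralaterally, at the smallest p that exact sign flips of 6 or 3 pairs can give (adjusted p = 0.1278, 0.4066 and 0.3879), so none could pass. Apart from the sides of the same mice, and the interaction, for which this was not checked, these libraries share only a number. Equal numbers did not all deviate together, and only between the sides of the same mice in endothelial-like cells did every library correlate best with its own number. Of the named genes 172 values stayed on their side of the threshold under the block and 17 passed no longer, Cd72 and Sult1a1 for CCI+HS against CCI among them. Where equal numbers did deviate together, it gave 7984 genes for male CCI in microglia-like cells and 0 for CCI+HS against CCI in endothelial-like cells (343 at an unadjusted p under 0.05).

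Without the libraries whose sex transcripts went against their labels the endothelial counts were 226 for CCI+HS, 1 for rCHI (Zbtb16), 4 contralaterally (Ackr1, Lcn2, Acer2 and Scgb3a1) and 364 in females. The astrocyte count was then 363, and the infiltrating share differed by 33.19 points after CCI+HS and 4.164 contralaterally, at the smallest p that 9 libraries can give. Without barcodes deeper in another library the endothelial counts were 11 contralaterally, 1345 in females and 1178 between the sides. Without cells holding over 10 UMIs of the homeostatic list they were 722 for male CCI, 220 for CCI+HS and 89 in females, and without cluster 23 they were 2459, 1096, 1399 in females and 30 contralaterally. Leaving out clusters 11, 14 and 28 gave 2268 microglial genes at 6 mo. At 7 d it gave 7001 but left mostly cluster 9 (887 cells), so it cannot check the 7 d calls. With cluster 7 added 7727 passed for male CCI. No named gene changed its call under either, and leaving out genes under 0.1 of another class gave 9 contralateral endothelial genes. The infiltrating share at 6 mo passed with stricter cells (0.508 points) and as a share of microglia-like plus infiltrating cells (1.434 points).

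With each library left out in turn the microglial counts ranged from 0 to 2 for rCHI, 0 to 6 for CCI+HS against CCI and 758 to 2778 contralaterally. The endothelial counts ranged from 223 to 644 for CCI+HS, 0 to 1 for rCHI, 0 to 2 for CCI+HS against CCI, 4 to 15 contralaterally, 219 to 1026 in females, 1133 to 2714 at 7 d and 132 to 2081 between the sides. Of 199 named genes past the threshold, 50 had a fold change moved by over 1.5 times without 1 library, 24 of them to a smaller one. The astrocyte count ranged from 130 to 363 and the oligodendrocyte count from 30 to 67. Differences in the infiltrating share ranged from 29.38 to 36.25 points after CCI+HS and from 2.93 to 5.7 contralaterally, all at the smallest p that 9 libraries can give, so the lost calls test no single library. They ranged from 0.2157 (without 7 d replicate 4) to 0.7671 at 7 d, past the threshold without 7 d replicate 2. At 6 mo they ranged from 0.1351 (without 6 mo replicate 1) to 0.4242, past it without 6 mo replicate 4.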

Other observations

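The tests of carried-over barcodes and of ipsilateral tissue on the contralateral side were chosen only after the results were seen. Microglia-like cells at 7 d also carried proliferation genes, of which 14 of 16 rose and 1 fell, 15 and 1 adjusted over the list alone (median log2 change 2.59, camera adjusted p = 9.26e-08; adjusted p = 0.0765 with an estimated correlation). In endothelial-like cells at 7 d 4 of 8 rose, Top2a, Birc5, Cenpf and Pcna, and 4 adjusted over the list alone (camera adjusted p = 4.94e-05; adjusted p = 0.0143 with an estimated correlation). On the contralateral side 7 of 16 disease-associated microglia genes rose and none fell, 7 adjusted over the list alone (camera adjusted p = 0.000274; adjusted p = 0.182 with an estimated correlation). The reactive astrocyte list rose in endothelial-like cells too: 10 of 12 genes after male CCI, 10 of 15 after CCI+HS and 10 of 12 at 6 mo, or 10, 13 and 11 adjusted over the list alone (camera adjusted p = 0.00187, 0.000704 and 0.00431 with an estimated correlation). In females 9 of 14 rose, 10 adjusted over the list alone (adjusted p = 0.0977 with an estimated correlation).

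Other classes shifted as well. B-like cells made up 0.931% of cells after male CCI and 0.120% in naive males (adjusted p = 0.0157), choroid plexus-like cells 11.2% and 23.8% (exact permutation test, adjusted p = 0.0388), endothelial-like cells 3.09% and 6.17% (adjusted p = 0.126) and pericyte-like cells 0.674% and 1.93% (adjusted p = 0.0644). At 6 mo endothelial-like cells made up 12.9% (adjusted p = 0.0639 against naive), and at 7 d neuroblast-like cells 1.16% against 0.540% (adjusted p = 0.126). The unnamed cluster 7 held 7.82% ± 3.66 of cells after CCI+HS, 4.82% ± 4.14 after male CCI and 4.03% after female CCI. It held 1.97% contralaterally, 1.81% in naive males, 1.07% in naive females, 0.969% after rCHI, 0.490% at 6 mo and 0.0471% at 7 d.

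Other splits of the same libraries into groups of the same sizes were refitted for each count of genes. In microglia-like cells 1 of 40 splits, the real one, gave as many genes for male CCI (7642, highest other 0), CCI+HS (5860, highest other 1), the contralateral side (2287, highest other 1), 7 d (7740, highest other 0) and 6 mo (5053, highest other 0). In endothelial-like cells the same held for male CCI (1573, 0), CCI+HS (383, 0), the contralateral side (17, 5), 7 d (1959, 1) and 6 mo (3307, 0), each with the highest other second. It held for astrocyte-like (225, 0) and oligodendrocyte-like cells (45, 9). Apart from the contralateral endothelial count, no other split drawn came near these counts, so a chance division of the libraries is unlikely for them. The contralateral endothelial count was 4 without the library labelled naive male 7. That is below both the 5 of another split and the 8 false calls of its simulated fit, so chance stays open for it. For CCI+HS against CCI in microglia-like cells the real split alone gave 2 genes (highest other 0). That margin is no larger than the 2 false calls of its simulated fit and was 0 without CCI+HS replicate 1, so chance stays open there. For rCHI all 40 splits reached the real count of 0, with at most 0 in microglia-like and 2 in endothelial-like cells. For the interaction all 40 reached 0, with at most 76 and 6, and for CCI+HS against CCI in endothelial-like cells all 40, with at most 35. The median over the other splits was 0 in these, so the splits with 76 and 35 genes may point to a structure of the samples other than the groups, which was not tested. Among other splits that part as many pairs of equal numbers as the real one, 2 for male CCI in microglia-like cells and 3 for CCI+HS against CCI in endothelial-like cells, the highest count was 0. Females gave 10 splits (5829 and 861 genes, highest other 0 in both) and the sides of the same mice 4 (6270 and 772, highest other 0 in both), too few for a share under 0.05.

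Contralateral libraries held infiltrating cells and changed microglial genes. Barcodes carried over from a deeper library did not account for either, since without them the share still differed from naive by 4.50 points and 2345 microglial genes passed. Nor did ipsilateral tissue in the samples account for the genes: over 487 genes that rose ipsilaterally, the median contralateral part of the rise was at least 3.08 times what the infiltrating share allows in each of the 3 mice. A response of microglia away from the contusion may remain, as a hypothesis found and tested on the same data. Blood carried in the vessels was not tested.

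Endothelial-like cells held transcripts of homeostatic microglia genes, most in naive libraries. Free microglial RNA in every droplet was excluded as the whole cause, since naive endothelial-like cells held 11.7 times as many of these UMIs as choroid plexus-like cells (4.29 to 27.9 over 7 libraries). Droplets holding a microglial and an endothelial cell could account for it, since the top 10% of cells held 62.4% of these UMIs (48.1% to 95.2%). Cells with over 10 such UMIs made up 27.6% of the class in naive males, 8.18% after male CCI and 2.11% at 6 mo. No biological explanation was tested.

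At 7 d 193 genes rose alike in microglia-like, endothelial-like and choroid plexus-like cells. A different annotation behind those files could account for part, since 19.7% of them overlap a gene that the longer list lacks, against 1.87% of all genes. Free RNA from another class could account for part too, since 72.5% stood at least 5 times higher in 1 class than in the lowest of the 3, against 38.3% of the 9408 genes over 3 CPM in each of the 3. That is no measure of how many of them it explains, since genes at large often meet it. Of the 193 genes 17 met both and 32 neither. Time after injury and library batch cannot be told apart here, and a biological change shared by the classes stays open as untested.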
